A study of Homo sapiens with 15 samples.

How the data were processed

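The series measured messenger RNA by sequencing in 15 libraries of Reh, a human B-lymphoblastic leukaemia cell line that carries the ETV6::RUNX1 fusion and has lost its normal ETV6. The libraries fall into 5 groups of 3. In 9 libraries the cells carried a doxycycline-inducible vector for V5-tagged wild-type ETV6, for V5-tagged ETV6 with the R399C substitution, or for the fluorescent protein tagBFP, and had received 500 ng/ml doxycycline for 48 h. In the other 6, cells with inducible dCas9-KRAB, a repressor fused to inactive Cas9 (CRISPR interference), carried a guide against the ERG promoter or a non-targeting guide, were sorted for the guide vector's fluorescent reporter, and had received 500 ng/ml doxycycline for 72 h. The groups are called ETV6_WT, ETV6_R399C, tagBFP, sgERG and sgCtrl below. Per the labels, RNA was isolated on columns with DNase treatment and the libraries were made with a kit that keeps the strand of the RNA.

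The deposited values are 1 table per library from Salmon, with an estimated count of reads per transcript, TPM, length and effective length, per the file headers. Version 0.11.3 of Salmon and the build hg38 are named in the submitters' processing notes. The strand setting, the bias options and the read filters are not given in the sources used here. The deposited estimated counts were not normalized between libraries, and the deposited TPM values have the same total in each library. Salmon shares reads that match several transcripts between them, so genes that overlap on a strand, near-identical family members and, since the strand setting is not given, antisense partners can exchange reads. Such genes are named as uncertain where they appear.

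Each table listed 167268 transcripts. Of these, 90.3% were found in GENCODE release 29 by their identifier without its version, and the rest, which held 6.67% to 7.56% of the reads of a library, were left out because the annotation used here does not name their genes. Estimated counts were summed over the transcripts of each of 33367 genes and rounded to whole numbers. Protein-coding genes held 99.09% of these reads. Coordinates are those of GENCODE 29 on hg38. Library totals ran from 22040338 to 52481351 reads. No pair of replicates of a group agreed within sampling noise, with a chi-square per degree of freedom of 2.83 to 14.72, so all 15 libraries were counted singly. Nothing in the labels says that the replicates were separate cultures, and p-values therefore measure only the spread between these libraries.

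The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The ETV6_WT, ETV6_R399C and tagBFP libraries entered 1 fit of 9 libraries, and sgERG and sgCtrl 1 fit of 6 libraries. CPM values are relative to the reads of named genes after TMM scaling, and RPM values, used for single transcripts, to all reads of a library. The SE of a log2 fold change was taken as its size divided by the square root of the test's F statistic. It thus restates the test and is not a separate measure of spread. The biological coefficient of variation was 4.95% in the first fit and 6.24% in the second. Data were simulated from the mean levels and spread of all 9 libraries of the first fit, with known changes in ETV6_WT (5 draws, 14068 genes). The test recovered 40.9% of genes changed 1.2-fold, 68.9% at 1.5-fold, 77.8% at 2-fold and 91.1% at 4-fold, and 8.2% of its calls were unchanged genes. For sgERG and sgCtrl (13347 genes) it recovered 37.5%, 74.9%, 88.2% and 97.6%, with 8.5% of calls on unchanged genes. DESeq2 1.42.0, an alternative, gave 12.8% and 11.2% of calls on unchanged genes. Far fewer genes were changed in the simulations than were called in the real comparisons, so these shares may not hold for the real data.

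The groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Named are ETV6 and ERG. From ETV6_WT against tagBFP and sgERG against sgCtrl come the 10 protein-coding genes with the largest rise and the 10 with the largest fall, and from each of the other comparisons 5 and 5. They had to pass the test, average at least 5 CPM and have all libraries of one group above all of the other. Up to 4 members of each list with the smallest p, the 10 genes with the largest changes shared by the 2 experiments and the 5 largest in opposite directions complete the rule. Not all of them are printed, and some genes are not reported here. RUNX1, and any other gene outside the rule, is said to be so where it is named.

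The 26 lists hold 399 genes, of which 391 were in the table. They cover genes reported as high in ETV6::RUNX1 leukaemia, targets of GGAA-repeat enhancers in Ewing sarcoma, the ETS family, B-lineage identity, MHC class II, stem and progenitor cells, JAK-STAT feedback, interferon response, p53 targets, endoplasmic reticulum (ER) and amino-acid stress, cell cycle, MYC and ribosome biogenesis, cholesterol synthesis, mitochondrially encoded genes, hypoxia and glycolysis, the BCL2 family, MAPK and immediate-early genes, NF-kB targets, adhesion and migration, megakaryocytes and platelets, endothelium, neighbours of ERG on chromosome 21, T cells, myeloid cells, erythroid cells and stroma. None was chosen on these samples. Lists with at least 5 tested genes were tested with camera of limma 3.58.1, which asks whether a list moved relative to all other genes, with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, and Benjamini-Hochberg adjustment over the lists of a comparison. The correlation estimated from the residuals of these libraries and fry, which asks whether a list's genes move one way on balance without comparing them with others, were alternatives.

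Genes called with ETV6_WT were tested as sets in the sgERG fit with camera, and the overlap of calls with Fisher's exact test, two-sided, with 95% intervals. Fisher's test counts genes, which are not independent, so its p-values and intervals do not measure the spread between libraries. For ETV6_WT and ETV6_R399C, which share the tagBFP libraries, 20 simulations of unchanged groups gave the correlation, covariance and overlap that the shared libraries produce with no effect.

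Alternatives tried were median-of-ratios scaling, DESeq2, no filter, a filter of 1 CPM in 3 libraries, an average transcript length offset as in tximport, the replicate number as a block, only the 2 groups compared in the fit, all 15 libraries in 1 fit, protein-coding genes only, a 2-fold threshold and leaving out each library in turn. Gene sets defined by ETV6_WT against ETV6_R399C or by a 2-fold change, genes called against both tagBFP and ETV6_R399C, and list medians after removal of a trend over GC content and length were added after seeing the data. Tables were joined and exact permutation tests on single values were run in python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures used matplotlib 3.10.9.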

Results

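Gene expression was measured in 15 libraries of the B-lymphoblastic leukaemia line Reh, in 5 groups of 3. Wild-type ETV6, ETV6 R399C or tagBFP had been induced for 48 h in 9 libraries, and dCas9-KRAB with a guide against the ERG promoter or a non-targeting guide for 72 h in 6. ETV6 is a transcriptional repressor of the ETS family and R399C lies in its DNA-binding domain. Totals were 23324816 to 28299476 reads with ETV6_WT, 22040338 to 27423208 with ETV6_R399C and 25897834 to 34046795 with tagBFP. They were 31881225 to 35735920 with sgERG and 39873358 to 52481351 with sgCtrl. Mitochondrially encoded genes took 0.96% to 1.42% of the reads in the first 3 groups and 2.58% to 3.3% in the CRISPR interference groups.

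ETV6 (chromosome 12, 11649854 to 11895402, forward strand, hg38) stood at 5.86 ± 0.327 CPM with tagBFP, 486 ± 18.1 with ETV6_WT and 373 ± 14.7 with ETV6_R399C (SD, n = 3 each). These were rises of 82.5-fold (log2 6.37 ± 0.06 SE, adjusted p = 2.0e-14) and 63.3-fold (log2 5.99 ± 0.06 SE, adjusted p = 4.2e-14) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The wild-type form was the more abundant transcript, by a log2 difference of 0.38 ± 0.04 SE (edgeR adjusted p = 2.5e-05). ERG, an ETS-family transcriptional activator (chromosome 21, 38380027 to 38661780, reverse strand), fell from 525 ± 6.35 CPM with sgCtrl to 105.1 ± 4.14 with sgERG, which is 20% of the control (log2 -2.32 ± 0.04 SE, edgeR adjusted p = 9.2e-10). The count assigned to ETV6 also fell with sgERG, from 13.2 ± 1.26 to 6.56 ± 0.513 CPM (49.9% of the control, edgeR adjusted p = 7.0e-05). The line has lost its normal ETV6, and reads from the ETV6 part of fusion transcripts would be counted there. The fall is therefore not a measure of a normal ETV6 transcript. ERG was 0.12 higher on the log2 scale with ETV6_WT than with tagBFP (± 0.03 SE, edgeR adjusted p = 0.0032) and differed by 0.00 with ETV6_R399C (edgeR adjusted p = 0.981).

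**Figure D1:**
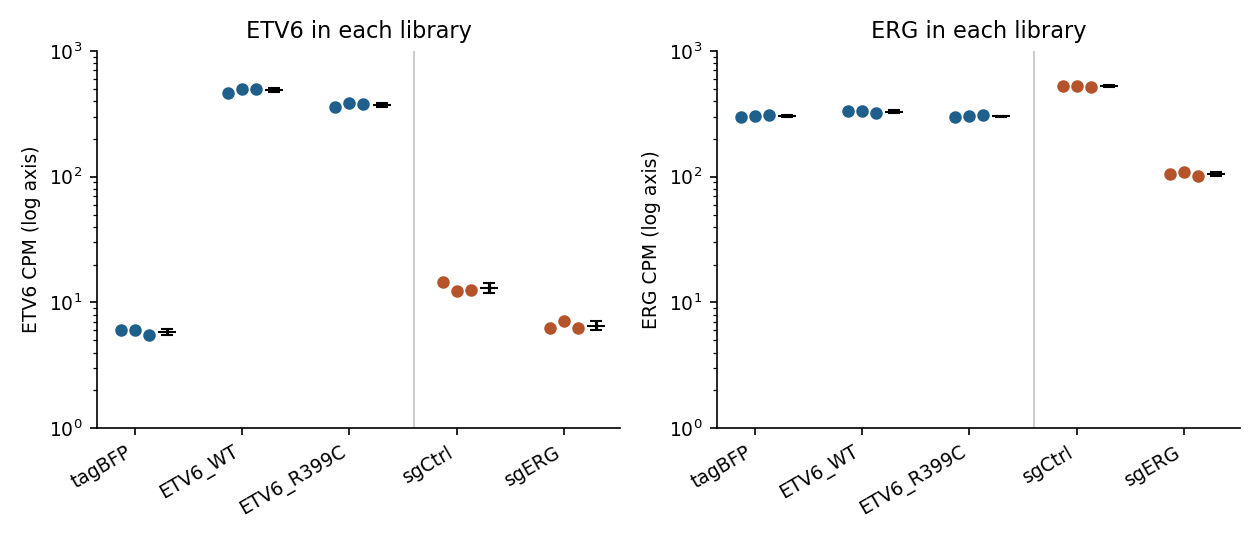
ETV6 (left) and ERG (right) in CPM on a log axis, 1 point per library and, beside the points, the mean with its SD (n = 3), with the inducible-protein libraries in blue and the CRISPR interference libraries in orange. ETV6 means were 486 and 373 CPM in the ETV6 groups against 5.86 with tagBFP, and ERG means 105.1 with sgERG against 525 with sgCtrl.

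The reads of ERG transcripts differed between start sites in how much lower they were with sgERG, a difference between sites that was not tested. The 5 annotated transcripts that start between 38498442 and 38498483 held 446 ± 6.62 RPM with sgCtrl and 79.9 ± 4.28 with sgERG, 17.9% of the control (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The 7 transcripts that start between 38660667 and 38661780 held 23.1 ± 0.71 and 12.5 ± 2.76 RPM, 54.0% of the control (exact permutation p = 0.1). The other 4, with starts from 38445621 to 38584945, held 16.5 ± 1.28 and 6.21 ± 3.16 RPM, 37.6% of the control (exact permutation p = 0.1). Not every transcript followed its group. In the first group ERG-214 stood at 4.66 ± 0.739 TPM with sgCtrl and 4.48 ± 0.91 with sgERG (SD, n = 3). In the second, ERG-215 stood at 0.792 ± 0.131 and 2.58 ± 0.245 TPM, and ERG-207 at 3.21 ± 0.176 and 4.69 ± 1.49 TPM. In the third, ERG-206 stood at 0.02 ± 0.035 and 0.533 ± 0.637 TPM. These differences were not tested. Salmon divides reads between transcripts that share exons, so these values depend on its model. RUNX1, which was chosen after its values were seen, fell from 611 ± 23.7 to 440 ± 7.27 CPM with sgERG (log2 -0.47 ± 0.04 SE, edgeR adjusted p = 2.3e-05). It was higher with ETV6_R399C than with tagBFP by 0.40 on the log2 scale (± 0.05 SE, edgeR adjusted p = 3.4e-05). Reads from the RUNX1 part of fusion transcripts would be counted to RUNX1, so these need not be changes of the normal gene.

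The first comparison asked what wild-type ETV6 changes in cells that lack it. The tetraspanins CD82 and CD9 rose 6.19-fold and 4.27-fold with ETV6_WT over tagBFP, from 27.4 ± 2.16 to 169 ± 3.84 CPM and from 6.41 ± 0.957 to 27.1 ± 1.17 CPM (SD, n = 3). SH3TC1, which encodes a protein with SH3 and tetratricopeptide domains, rose from 129 ± 7.13 to 566 ± 4.20 CPM, and CCND2, which encodes the cell-cycle regulator cyclin D2, from 3.14 ± 0.407 to 13.4 ± 0.911 CPM. The fatty acid desaturase gene SCD fell 8.41-fold, from 74.1 ± 2.80 to 8.83 ± 0.560 CPM. CLIC5, an intracellular chloride channel gene known to be high in ETV6::RUNX1 leukaemia, fell 7-fold, from 42.7 ± 3.04 to 6.13 ± 0.505 CPM, and BIRC7, which encodes an inhibitor of apoptosis, fell 4.31-fold, from 60.8 ± 2.25 to 14.1 ± 0.728 CPM.

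Among the other large rises were AFF3 (log2 2.53 ± 0.28 SE), the scaffold gene AHNAK (2.39 ± 0.16) and the semaphorin gene SEMA6A (2.21 ± 0.12), with edgeR adjusted p of at most 3.0e-05. Apart from ETV6, TIAF1 had the largest rise among genes that met the naming rule (2.96 ± 0.05). RAPGEF3, an exchange factor gene for RAP1, rose by 2.00 ± 0.16 and TIFAB by 1.96 ± 0.07. TIAF1 lies within MYO18A, TIFAB overlaps DCANP1 and RAPGEF3 overlaps SLC48A1 on the other strand, so their reads are uncertain. Large falls were measured for RUFY4 (log2 -2.57 ± 0.17), the sialic acid-binding lectin gene SIGLEC15 (-2.56 ± 0.12) and RAP1GAP (-2.14 ± 0.11), all at edgeR adjusted p of 5.2e-07 or below. CYBB, which encodes the NADPH oxidase subunit of phagocytes (-2.48 ± 0.08), the organic solute transporter gene SLC51A (-2.45 ± 0.08) and RERGL (-2.26 ± 0.10) also fell, and each overlaps another annotated gene, CYBB on its own strand and SLC51A and RERGL on the other.

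In all, 5202 of 14242 genes passed the threshold, 2505 higher and 2697 lower with ETV6_WT, and 382 of them changed at least 2-fold (241 higher, 141 lower). The median size of a called change was 0.26 on the log2 scale, and in 48.2% of tested genes all libraries of one group lay above all of the other, where chance gives 10%. With an average transcript length offset 2913 genes passed.

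B-lineage genes rose with ETV6_WT: 20 of 25 tested members were higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 3.9e-10, adjusted p = 0.00668 with an estimated correlation). They included MME, which encodes the CD10 antigen (log2 0.96 ± 0.03 SE), the B-cell receptor subunit gene CD79B (0.68 ± 0.03), the transcription factor gene POU2F2 (1.92 ± 0.07) and CD24 (0.70 ± 0.03). MYC and ribosome biogenesis genes fell, 15 of 16 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 3.2e-07, adjusted p = 0.163 with an estimated correlation). MYC itself (-0.46 ± 0.03) and ODC1, the first enzyme of polyamine synthesis (-0.44 ± 0.04), were among them.

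Of 18 tested genes reported as high in ETV6::RUNX1 leukaemia, 10 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 3.9e-04, adjusted p = 0.103 with an estimated correlation). Beside CLIC5 and BIRC7, the potassium channel gene KCNN1 fell by 1.34 ± 0.04 SE and PIK3C3, the class III phosphatidylinositol 3-kinase gene, fell by 0.88 ± 0.03 on the log2 scale. Adhesion and migration genes were higher in 8 of 13 and lower in 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 3.9e-04, adjusted p = 0.064 with an estimated correlation). The integrin genes ITGA4 (0.62 ± 0.04) and ITGA6 (0.78 ± 0.06) rose. Interferon-response genes were higher in 13 of 19 and lower in 3, the same adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.163 with an estimated correlation). IFIT2 rose by 1.28 ± 0.06 and MX1 by 0.56 ± 0.04, and IFITM1 fell by 0.98 ± 0.05 on the log2 scale.

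Cholesterol synthesis genes fell in 8 of 15 and rose in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 8.8e-04, adjusted p = 0.354 with an estimated correlation). DHCR7 (-0.57 ± 0.05) and LSS (-0.42 ± 0.04), both sterol-pathway enzymes, fell. Genes of ER and amino-acid stress fell in 10 of 15 and rose in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.354 with an estimated correlation). The cystine transporter gene SLC7A11 (-1.07 ± 0.05), the serine synthesis gene PSAT1 (-0.62 ± 0.05) and CHAC1, which degrades glutathione (-0.69 ± 0.07), fell, and XBP1, which encodes a transcription factor of the unfolded protein response, rose (0.60 ± 0.03).

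NF-kB targets rose in 4 of 11 and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0172, adjusted p = 0.161 with an estimated correlation). The inhibitor genes TNFAIP3 (0.54 ± 0.03) and NFKBIA (0.22 ± 0.03) rose. ETS-family genes rose in 9 of 19 and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0398, adjusted p = 0.224 with an estimated correlation). In this list the median was 0.12 and the mean -0.04 on the log2 scale, and the test pointed up. ELK3 (0.81 ± 0.03) and SPIB (0.83 ± 0.04) rose and ETV4 (-2.72 ± 0.17) fell. The call of the ETS family ended without either of ETV6_WT replicates 1 and 2 (camera adjusted p = 0.0732 and 0.0658) or of tagBFP replicates 1 and 2 (0.0504 and 0.0666). It also ended with the replicate number as a block. Mitochondrially encoded genes fell in 3 of 13 and rose in 0, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0398, adjusted p = 0.655 with an estimated correlation). MT-CO3 stood at -0.30 ± 0.07. The mitochondrial call ended without ETV6_WT replicate 1 (camera adjusted p = 0.208), ETV6_WT replicate 2 (0.0769) or tagBFP replicate 3 (0.206).

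Other lists had no call in camera with ETV6_WT over tagBFP. Higher and lower members were 6 and 3 of 18 p53 targets, 3 and 1 of 12 BCL2-family genes, 3 and 1 of 20 cell cycle genes, 2 and 0 of 5 endothelial genes, 4 and 2 of 8 neighbours of ERG, 2 and 1 of 10 targets of GGAA repeats, and 3 and 7 of 14 hypoxia and glycolysis genes. They were 2 and 2 of 11 JAK-STAT feedback genes, 2 and 5 of 15 MAPK and immediate-early genes, 2 and 0 of 6 megakaryocyte genes, 2 and 0 of 6 myeloid genes, 3 and 2 of 9 stem and progenitor genes and 1 and 1 of 5 T-cell genes. Adjusted over the list alone, the higher members were 4 of the BCL2 family, 3 of the endothelial list, 3 of the JAK-STAT list and 3 of the megakaryocyte list, which then also had 1 lower. BTG2, a growth-arrest gene among the p53 targets, rose by 1.34 ± 0.04 SE, and SOCS2, a feedback inhibitor of JAK-STAT signalling, by 1.01 ± 0.04. The MAPK phosphatase gene DUSP6 (-0.55 ± 0.03) and SPRED2, an inhibitor of the same pathway (-1.19 ± 0.07), fell. In lists too short for camera, all 3 tested MHC class II genes, 1 of 2 stromal genes (PDGFRB) and 0 of 1 erythroid genes were higher, and the erythroid gene SLC4A1 was lower (log2 -0.61 ± 0.18), all also adjusted over the list alone. PDGFRB missed the threshold without any 1 of the 6 libraries (edgeR adjusted p of 0.0783 to 0.199), and SLC4A1 missed it with the transcript length offset (0.659) and without ETV6_WT replicate 1 (0.0589), tagBFP replicate 1 (0.0597) or tagBFP replicate 3 (0.0519). The MHC class II gene HLA-DRA missed the threshold with the replicate number as a block.

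The second comparison asked the same of ETV6 R399C. SCD fell 11.7-fold against tagBFP, to 6.37 ± 0.534 CPM, and RUFY4 8.03-fold, from 9.23 ± 0.437 to 1.14 ± 0.244 CPM (SD, n = 3). CD9 rose 6.08-fold, to 38.7 ± 0.526 CPM, CD82 3.9-fold, to 106.5 ± 3.14 CPM, and BEST3, a bestrophin channel gene, 4.12-fold, from 20.9 ± 0.417 to 86.5 ± 2.88 CPM. AFF3 rose by 2.06 ± 0.28 SE on the log2 scale, and the ephrin receptor gene EPHA7 fell by 2.25 ± 0.13 (edgeR adjusted p = 1.5e-04 and 2.6e-07). TIAF1 (2.85 ± 0.05), TIGD5 (-1.52 ± 0.09) and the lysosomal iduronidase gene IDUA (-1.46 ± 0.07) passed too, and each overlaps another gene, TIGD5 and IDUA on the other strand. The counts were 5826 of 14242 genes, 2673 higher and 3153 lower, with 301 changed at least 2-fold (222 higher, 79 lower) and a median called change of 0.27. With the transcript length offset 3427 genes passed.

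SCD differed between the experiments as well. It had 1705 to 2439 reads in each tagBFP library, 0 to 4 reads in each sgCtrl library and 0 reads in the sgERG libraries. For sgERG this allows up to 0.0312 CPM without TMM scaling over the group (a limit of 3 reads that covers counting error only).

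With ETV6_R399C, B-lineage genes again rose, 21 of 25 higher and 1 lower, or 22 and 1 adjusted over the list alone (camera adjusted p = 1.5e-10, adjusted p = 0.006 with an estimated correlation). MME rose by 0.79 ± 0.03 SE and BACH2, a transcription factor gene of B cells, by 1.08 ± 0.05 on the log2 scale. MYC and ribosome biogenesis genes fell in 15 of 16 and rose in 0, also adjusted over the list alone (camera adjusted p = 4.1e-09, adjusted p = 0.132 with an estimated correlation). MYC fell by 0.46 ± 0.03 and SRM, the spermidine synthase gene, fell by 0.60 ± 0.05. Cholesterol synthesis genes rose, 12 of 15 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 6.1e-06, adjusted p = 0.26 with an estimated correlation). HMGCS1, an early enzyme of the pathway (0.49 ± 0.04), FDFT1 (0.33 ± 0.03) and INSIG1 (0.50 ± 0.05) rose. Genes of ER and amino-acid stress rose in 10 of 15 and fell in 2, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.005, adjusted p = 0.34 with an estimated correlation). CHAC1 (0.52 ± 0.06) and DDIT4 (0.64 ± 0.09) were higher.

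Adhesion genes rose in 8 of 13 and fell in 1 with ETV6_R399C, also adjusted over the list alone (camera adjusted p = 0.00183, adjusted p = 0.102 with an estimated correlation). ETS-family genes rose in 10 of 19 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00702, adjusted p = 0.132 with an estimated correlation). In the ETS family SPIB rose by 0.70 ± 0.04 and SPI1, which encodes PU.1, by 0.38 ± 0.03. NF-kB targets rose in 7 of 11 and fell in 0, also adjusted over the list alone (camera adjusted p = 0.0092, adjusted p = 0.132 with an estimated correlation). Myeloid genes rose in 3 of 6 and fell in 0, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0431, adjusted p = 0.18 with an estimated correlation), with the myeloperoxidase gene MPO at 0.94 ± 0.04. The myeloid call ended without ETV6_R399C replicate 2 (camera adjusted p = 0.0681), tagBFP replicate 1 (0.0602) or tagBFP replicate 2 (0.0634), and with the replicate number as a block. Of the genes reported as high in ETV6::RUNX1 leukaemia, 4 rose and 9 fell of 18, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.176).

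The direct comparison of the wild-type with the R399C form tested the difference between their effects. CLIC5 stood at 6.13 ± 0.505 CPM with ETV6_WT and 43.0 ± 0.665 with ETV6_R399C, close to the 42.7 ± 3.04 with tagBFP (SD, n = 3). SIGLEC15 was 5.06-fold lower with ETV6_WT (2.14 ± 0.212 against 10.8 ± 0.463 CPM). CYBB (log2 -2.53 ± 0.08 SE) and SLC51A (-2.22 ± 0.08) were lower too, with the overlaps named above. CCND2 was 3.36-fold higher with ETV6_WT (13.4 ± 0.911 against 3.98 ± 0.265 CPM), TBX21, which encodes the transcription factor T-bet, 3.4-fold (11.6 ± 1.43 against 3.43 ± 0.341 CPM) and SERHL2 2.81-fold (16.9 ± 0.603 against 5.99 ± 0.126 CPM). CPZ (1.79 ± 0.14) and RAPGEF3 (1.56 ± 0.16) were higher too, and CPZ shares its locus with GPR78. The test called 3044 of 14242 genes, 1721 higher and 1323 lower with ETV6_WT, and 203 at least 2-fold (68 higher, 135 lower). It called 1236 with the transcript length offset, 2008 without ETV6_R399C replicate 1 and 2009 without ETV6_WT replicate 2.

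**Figure D2:**
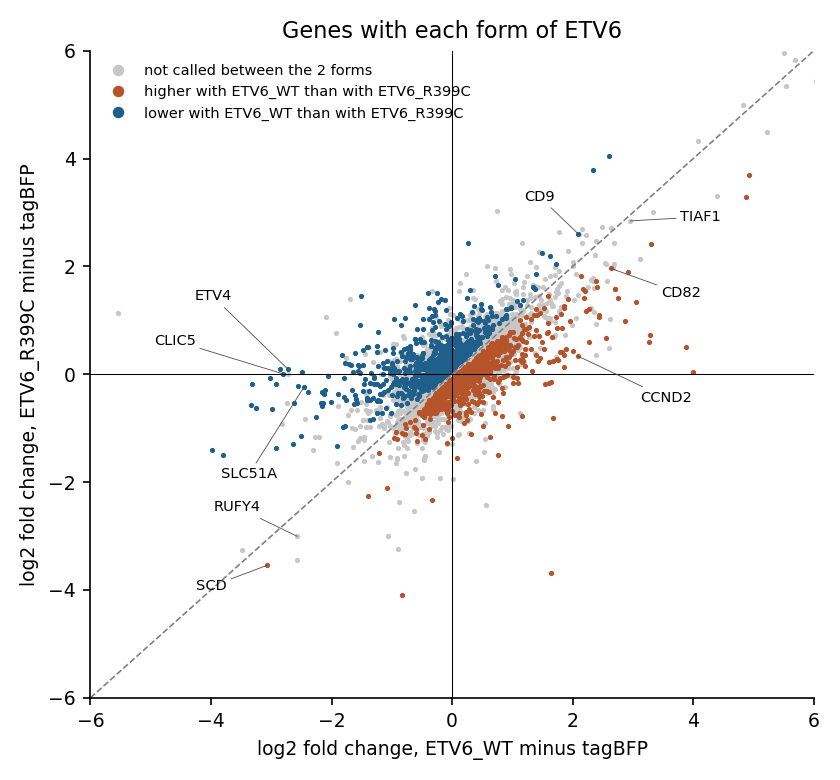
Log2 fold change of each gene with ETV6_WT (horizontal) and with ETV6_R399C (vertical), both against tagBFP, with genes called between the 2 forms in colour and the dashed line marking equal change (16 of 14241 genes lie outside the axes, and ETV6 is left out). SCD, RUFY4, TIAF1, CD9 and CD82 lie far from 0 on both axes, whereas CLIC5 and SLC51A lie far from 0 with ETV6_WT and near 0 with ETV6_R399C.

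Both forms changed many genes the same way against tagBFP. Of the genes lower with ETV6_WT, 1888 (70%) were also lower with ETV6_R399C, where independent lists of these sizes would share 597.1. Of those higher, 1689 (67.4%) were shared, against 470.1. The 2 comparisons use the same tagBFP libraries. Simulated unchanged groups against those libraries shared 0 calls in 20 draws, where 3577 were observed, or 1825 with the transcript length offset. Unchanged groups are bound to give few calls, so this 0 does not measure how far the shared libraries raise the overlap of called genes. The correlation of fold changes across genes, which are not independent replicates, was r = 0.66 against a simulated mean of 0.48, and the covariance was 0.148 against 0.0255, a difference of 0.122. The covariance was 0.559 without the filter on low counts, and 0.161 to 0.246 with 1 library left out, the highest without tagBFP replicate 1; the simulated value was not computed for these. With 3 control libraries no split leaves 2 on each side, so part of the excess over independent lists may come from the shared controls. With 1 tagBFP library for one form and the other 2 for the other form, a division made after seeing the data, the covariance of differences in mean log2 CPM was 0.0798 to 0.0884, against 0.112 with all 3 shared.

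Genes that set the wild-type form apart were those called against tagBFP and, in the same direction, against ETV6_R399C, a set added after seeing the data. They numbered 1290, of which 607 were lower (22.5% of genes lower with ETV6_WT) and 683 higher (27.3% of genes higher).

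Cholesterol synthesis genes were lower with ETV6_WT than with ETV6_R399C in 14 of 15 and higher in 0, or 15 and 0 adjusted over the list alone (camera adjusted p = 8.1e-15, adjusted p = 0.14 with an estimated correlation). HMGCS1 was lower by a log2 difference of -0.63 ± 0.04 SE, LSS by -0.60 ± 0.04 and the squalene epoxidase gene SQLE by -0.46 ± 0.03. Genes of ER and amino-acid stress were lower in 12 of 15 and higher in 1, or 13 and 2 adjusted over the list alone (camera adjusted p = 3.5e-09, adjusted p = 0.158 with an estimated correlation). SLC7A11 was at -1.18 ± 0.05, CHAC1 at -1.21 ± 0.07 and the asparagine synthetase gene ASNS at -0.66 ± 0.05. Genes reported as high in ETV6::RUNX1 leukaemia were lower in 11 of 18 and higher in 2, also adjusted over the list alone (camera adjusted p = 5.7e-06, adjusted p = 0.125 with an estimated correlation). BIRC7 was at -1.82 ± 0.05 and KCNN1 at -1.35 ± 0.04.

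Interferon-response genes were higher with ETV6_WT than with ETV6_R399C in 11 of 19 and lower in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 3.4e-04, adjusted p = 0.14 with an estimated correlation). IFI6 was at 0.51 ± 0.07 and MX2 at -0.44 ± 0.05. Cell cycle genes were higher in 7 of 20 and lower in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.00135, adjusted p = 0.406 with an estimated correlation). Against tagBFP, 11 of the 20 were lower and 2 higher with ETV6_R399C, also adjusted over the list alone, with no call for the list (camera adjusted p = 0.0907, or 0.0326 without ETV6_R399C replicate 3), and 1 was lower and 3 higher with ETV6_WT. MYC and ribosome biogenesis genes were higher in 9 of 16 and lower in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.406 with an estimated correlation). MCM4, a replication licensing gene of the cell cycle list, was higher by 0.21 ± 0.03 on the log2 scale. BCL2-family genes were lower in 4 of 12 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.00639, adjusted p = 0.14 with an estimated correlation). The pro-apoptotic genes HRK (-0.91 ± 0.11), BBC3 (-0.61 ± 0.06) and BID (-0.49 ± 0.05) were lower. MAPK and immediate-early genes were lower in 6 of 15 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.146 with an estimated correlation). DUSP6 was at -0.73 ± 0.03 and JUN at -1.06 ± 0.12. The MAPK call ended without ETV6_R399C replicate 3 (camera adjusted p = 0.058). Of the lists that rose with both forms against tagBFP, B-lineage genes were not called between the forms (camera adjusted p = 0.976). There 8 of 25 were higher and 6 lower, or 10 and 8 adjusted over the list alone. Adhesion genes (3 higher and 3 lower of 13, camera adjusted p = 0.921) and NF-kB targets (2 and 3 of 11, camera adjusted p = 0.862) were not called either. In the ETS family ETV4 (-2.82 ± 0.17) and ETV5 (-1.68 ± 0.11) were lower, with no call for the family (camera adjusted p = 0.712), and ETV5 missed the threshold with the transcript length offset (log2 -1.06, edgeR adjusted p = 0.0562).

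**Figure D3:**
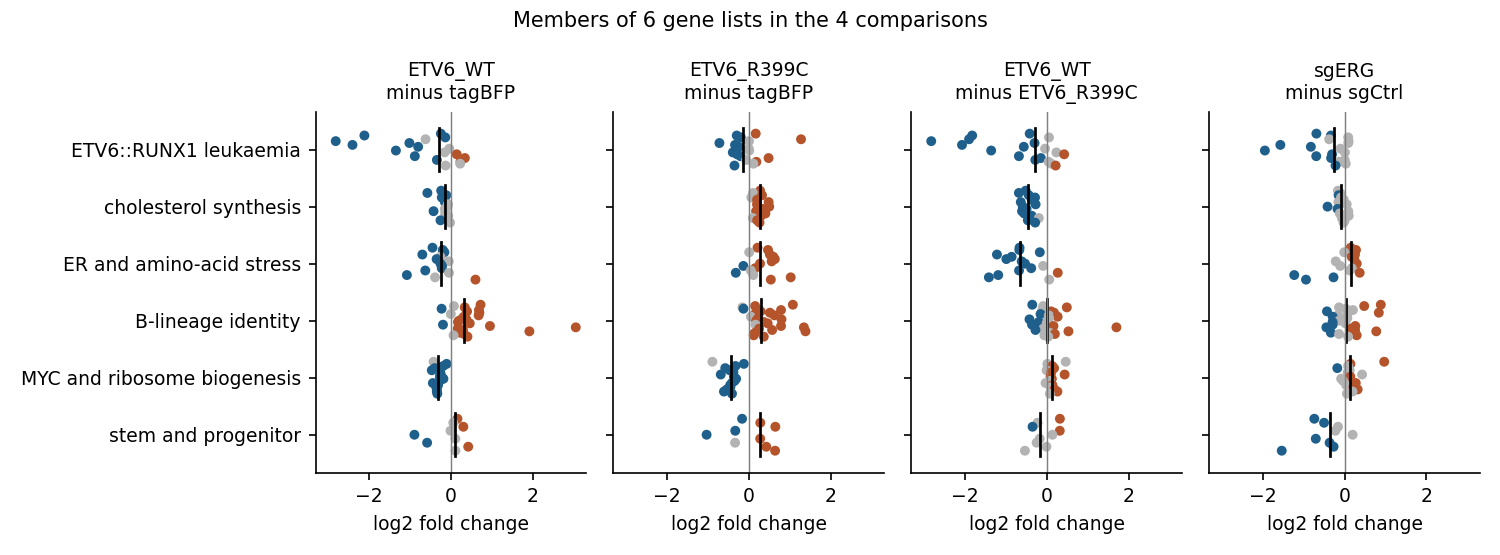
Log2 fold changes of the tested members of 6 gene lists in the 4 comparisons, 1 point per gene, in orange where higher, blue where lower and grey where not called, with the list median as a black bar. The cholesterol synthesis medians were -0.14 with ETV6_WT and 0.27 with ETV6_R399C against tagBFP, and -0.46 between the 2 forms.

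The CRISPR interference comparison asked what changes when the ERG promoter is repressed. GABRA4, a GABA receptor subunit gene, fell from 373 ± 3.92 CPM with sgCtrl to 84.1 ± 7.42 with sgERG (4.43-fold), and KCNN1 from 170 ± 6.49 to 44.3 ± 3.80 CPM (3.85-fold; SD, n = 3). The tetraspanin gene TSPAN9 fell 3.98-fold, from 122 ± 2.90 to 30.6 ± 2.06 CPM. OSR2, a zinc-finger transcription factor gene, rose 4.38-fold, from 14.8 ± 1.10 to 64.7 ± 4.13 CPM, and IKZF2, which encodes the Ikaros-family factor Helios, 2.99-fold, from 87.7 ± 2.46 to 262 ± 18.8 CPM. SPIB, an ETS gene of the B lineage, rose 3.2-fold, from 14.8 ± 0.61 to 47.2 ± 3.28 CPM.

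Further falls were those of the synaptic gene UNC13A (log2 -2.32 ± 0.16 SE), DPF3, a subunit gene of a chromatin remodeller (-2.12 ± 0.11), TRNP1 (-2.09 ± 0.08) and the metalloproteinase gene MMP15 (-1.93 ± 0.07), with edgeR adjusted p of at most 4.8e-06. KLC3 (-2.53 ± 0.11), ANGPTL2 (-2.27 ± 0.05) and SLC51A (-2.12 ± 0.07) fell as well, but each overlaps a gene on the other strand, as does GABRA4. Rises included PHLDA1 (1.90 ± 0.09), the secreted adenosine deaminase gene ADA2 (1.83 ± 0.09), PSD4 (1.67 ± 0.07) and the forkhead gene FOXO6 (1.61 ± 0.08), with edgeR adjusted p of at most 5.0e-07. MEF2B (2.25 ± 0.18) shares exons with a readthrough gene, SPIB overlaps another annotated gene, and the metallothionein genes MT1X (2.04 ± 0.10) and MT2A (1.60 ± 0.08) belong to a family of near-identical members, so these 4 are uncertain.

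The test called 1969 of 13464 genes, 927 higher and 1042 lower with sgERG, and 267 at least 2-fold (125 higher, 142 lower). The median called change was 0.35 on the log2 scale, and 34.6% of tested genes separated the groups, where chance gives 10%. It called 1160 genes without sgCtrl replicate 1 and 1162 without sgCtrl replicate 3. The library sgERG replicate 3 differed most from the others of its group (chi-square per degree of freedom 12.97 and 14.72, against 6.94 between the other 2), and 2302 genes were called without it.

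Stem and progenitor genes fell with sgERG in 6 of 9 and rose in 0, also adjusted over the list alone (camera adjusted p = 4.2e-04, adjusted p = 0.131 with an estimated correlation). They included the receptor gene FLT3 (log2 -0.74 ± 0.06 SE) and the transcription factor genes LMO2 (-0.70 ± 0.09), GFI1 (-0.50 ± 0.07) and MYB (-0.27 ± 0.03). Of the genes reported as high in ETV6::RUNX1 leukaemia 9 of 18 fell and 0 rose, or 10 and 0 adjusted over the list alone (camera adjusted p = 4.2e-04, adjusted p = 0.131 with an estimated correlation). KCNN1 (-1.95 ± 0.06), the erythropoietin receptor gene EPOR (-0.82 ± 0.06), PIK3C3 (-0.69 ± 0.04) and ARHGEF4 (-0.69 ± 0.05) fell. All 3 tested MHC class II genes fell, also adjusted over the list alone: the transactivator gene CIITA (-1.19 ± 0.04), CD74 (-0.91 ± 0.04) and HLA-DRA (-0.99 ± 0.05), with edgeR adjusted p of at most 3.3e-07, in a list too short for camera. HLA genes have alternate-haplotype copies in the annotation, so the value of HLA-DRA is uncertain.

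MYC and ribosome biogenesis genes rose with sgERG in 6 of 16 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.33 with an estimated correlation). MAPK and immediate-early genes rose in 8 of 16 and fell in 2, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.619 with an estimated correlation). EGR1, an immediate-early transcription factor gene, rose by 1.04 ± 0.15 SE, while DUSP6 (-0.97 ± 0.04) and SPRY2 (-0.47 ± 0.05), feedback inhibitors of the pathway, fell. Of 7 tested neighbours of ERG on chromosome 21, 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0306, adjusted p = 0.33 with an estimated correlation). ETS2 rose by 1.09 ± 0.03 and PSMG1 by 0.32 ± 0.05. Without sgERG replicate 1 the MAPK list and the neighbours of ERG were no longer called (camera adjusted p = 0.0769 for each), nor were the MAPK list without sgERG replicate 3 (0.0836) or with a stricter filter on low counts (0.0919), and the neighbours without sgCtrl replicate 2 (0.0545). The call of the neighbours also ended with the replicate number as a block. B-lineage genes went both ways, 8 of 25 higher and 6 lower, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.539), with BACH2 (0.89 ± 0.04) and CD24 (0.84 ± 0.06) higher and CD22 (-0.43 ± 0.04) and the recombination gene RAG1 (-0.33 ± 0.04) lower. BCL2, the anti-apoptotic founder of its family, fell by 0.81 ± 0.04.

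The last comparison asked whether the genes that wild-type ETV6 lowers also fall when ERG is repressed. The bile acid and steroid transporter gene SLC51A fell in both (log2 -2.45 with ETV6_WT and -2.12 with sgERG), as did SLC17A7, a vesicular glutamate transporter gene (-1.67 and -1.72), GABRA4 (-1.63 and -2.15), DPF3 (-1.59 and -2.12), MMP15 (-1.58 and -1.93) and KCNN1 (-1.34 and -1.95). IKZF2 rose in both (1.38 and 1.58), as did RASAL1, a regulator of RAS (1.42 and 1.40), and the lectin-like receptor gene CLEC2D (1.29 and 1.28). Opposite changes were measured for the DNA ligase gene LIG4 (1.59 with ETV6_WT and -1.14 with sgERG) and for CD9 (2.09 and -1.02). SEs were at most 0.11 and all of these passed edgeR's test in both experiments (n = 3 per group). KCNN1 did not pass with ETV6_R399C (0.02, edgeR adjusted p = 0.779), whereas IKZF2 (1.58) and CLEC2D (1.42) rose with ETV6_R399C. The other falls named here passed with ETV6_R399C as well but were smaller: GABRA4 (-0.54), MMP15 (-0.54), DPF3 (-0.47), SLC17A7 (-0.30) and SLC51A (-0.23).

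As a whole, the genes lower with ETV6_WT did not move 1 way with sgERG. Of 2675 such genes, 279 (10.4%) fell and 246 (9.2%) rose, with a median of 0.02 on the log2 scale (camera adjusted p = 0.23 over the 2 planned sets). Camera pointed up for this set and fry pointed down, and neither passed. Among 12825 genes tested in both experiments, the genes lower with ETV6_WT were enriched for genes lower with sgERG (odds ratio 1.48, 95% interval 1.27 to 1.71, Fisher's exact p = 2.5e-07, 279 shared where independent lists would share 212.7), and as much for genes higher with sgERG (odds ratio 1.48, 1.26 to 1.72). Of 2424 genes higher with ETV6_WT, 375 (15.5%) fell and 249 (10.3%) rose with sgERG (camera p = 0.0399, adjusted p = 0.0798, adjusted p = 0.0601 with an estimated correlation), and the odds ratios were 2.77 for genes lower and 1.72 for genes higher with sgERG. The last of these was 3.16 with the transcript length offset, 2.61 without sgCtrl replicate 1 and 2.81 without sgCtrl replicate 3. The correlation of the fold changes across 12823 genes was r = 0.04 and rho = -0.09.

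Genes lower by at least 2-fold with ETV6_WT, a set added after seeing the data, fell with sgERG. Of 131 tested in both, 58 (44.3%) fell and 20 (15.3%) rose, with a median of -0.34 on the log2 scale (camera adjusted p = 3.8e-06, adjusted p = 0.0154 with an estimated correlation). The odds ratio for genes lower with sgERG was 9.69 in this set, and 3.73 in genes lower with ETV6_WT than with ETV6_R399C, also a set added after seeing the data. That second set was enriched for genes higher with sgERG as well (odds ratio 2.66, 95% interval 2.23 to 3.16, 192 shared where independent lists would share 90.9). Of the 70 genes lower by at least 2-fold with ETV6_R399C, 13 fell and 8 rose with sgERG, and of the 164 higher by at least 2-fold with ETV6_R399C, 26 fell and 45 (27.4%) rose (camera adjusted p = 0.0926, fry adjusted p = 0.00201). Among the 184 genes higher by at least 2-fold with ETV6_WT, 36 fell and 33 rose (odds ratio 2.97 for genes higher with sgERG). Of the 123 genes at least 2-fold lower with ETV6_WT than with ETV6_R399C, 49 (39.8%) fell and 27 rose with sgERG (camera adjusted p = 0.0266, adjusted p = 0.151 with an estimated correlation). Of the 55 at least 2-fold higher, like the other 2-fold sets chosen after seeing the data, 17 (30.9%) also fell and 6 rose, with a median of -0.26 on the log2 scale (camera adjusted p = 0.0045, adjusted p = 0.151 with an estimated correlation). CLIC5, which fell 7-fold with ETV6_WT, had a log2 difference of 0.10 with sgERG and did not pass (edgeR adjusted p = 0.163).

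**Figure D4:**
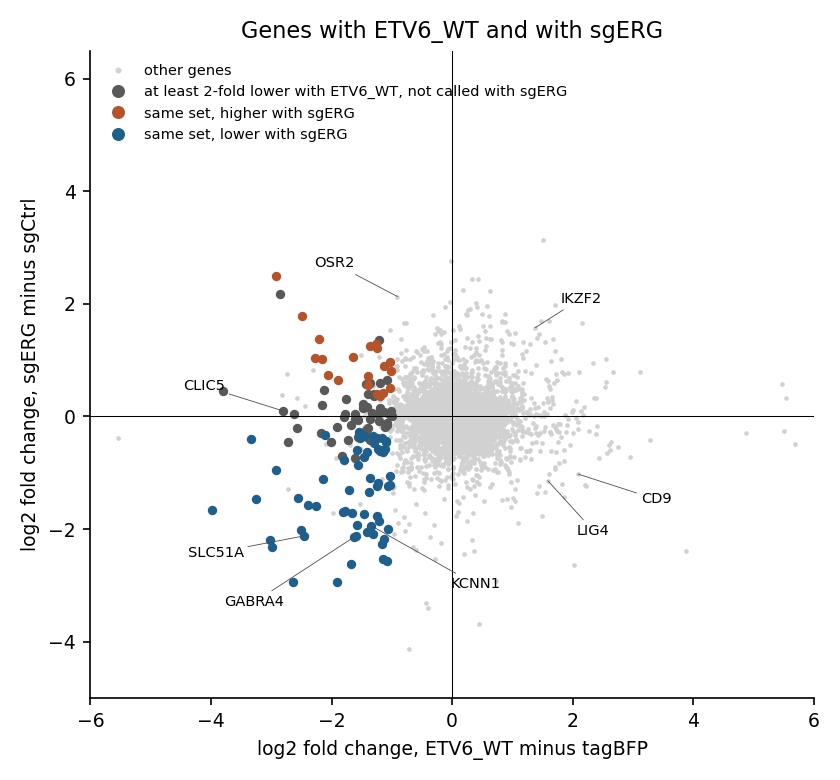
Log2 fold change of each gene with ETV6_WT against tagBFP (horizontal) and with sgERG against sgCtrl (vertical), with genes called and at least 2-fold lower with ETV6_WT as large points (9 of 12823 genes lie outside the axes, and ETV6 and ERG are left out). Of the 131 large points, 58 in blue fell and 20 in orange rose with sgERG.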

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

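The tests of scaling and of culture state for the cholesterol synthesis genes, the tests in the sgERG libraries of genes at least 2-fold lower or higher with ETV6_WT, the comparison with genes higher with sgERG, and the corrected list medians were chosen after the results were seen.

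Cholesterol synthesis genes moved in opposite directions with the 2 forms of ETV6 against tagBFP, and the direct comparison differed (camera adjusted p = 8.1e-15, adjusted p = 0.14 with an estimated correlation). Genes of ER and amino-acid stress did so too (camera adjusted p = 3.5e-09, adjusted p = 0.158 with an estimated correlation). With an estimated correlation neither list passed against tagBFP either, with adjusted p = 0.354 for ETV6_WT and 0.26 for ETV6_R399C in the first list and adjusted p = 0.354 and 0.34 in the second. In all, 151 genes were called in opposite directions with the 2 forms. Each of the 151 was also called between ETV6_WT and ETV6_R399C, which was close to fixed in advance, since that comparison is the difference of the other 2. Of these, 48 were higher with ETV6_WT and lower with ETV6_R399C. The rest, which went the other way, included the cholesterol synthesis genes HMGCS1, SQLE, FDFT1, LSS and CYP51A1, and the stress genes ATF3, HERPUD1, ASNS, CHAC1, PHGDH and DDIT4, which are named here because of their values.

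For the cholesterol synthesis genes, GC content and transcript length do not account for the whole pattern, since the list's median was -0.46 before and -0.44 after their trend was removed. A scaling error between libraries would move all genes alike, but the list's median lay -0.476 from that of all genes (quartiles -0.583 to -0.341), with 15 of 15 members below. The culture state of the separate cell populations stays open: with the correlation between these genes estimated across libraries of a group, adjusted p was 0.14, and the labels do not separate a construct from its population. A difference between the wild-type and the R399C protein also stays open and was not tested apart from it.

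Many genes changed the same way with both forms against tagBFP. Chance values shared through the tagBFP libraries do not account for the whole pattern, since the covariance of the fold changes was 0.148 and the highest of 20 simulated values 0.0327. A drift of the tagBFP cells alone would leave the sgCtrl cells nearer the ETV6 groups, and for 68.5% of 149 genes changed at least 2-fold with both forms (exact Clopper-Pearson 95% interval 60.3 to 75.8) sgCtrl lay nearer tagBFP. The sgCtrl cells may not stand for tagBFP cells without drift, since SCD had 0 to 4 reads in each sgCtrl library and 1705 to 2439 in each tagBFP library. The interval treats genes as independent, which they are not, and it reaches both sides of the 70% set as the bound beforehand. The drift therefore cannot be told apart from an effect shared by both forms.

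Genes lower with ETV6_WT overlapped genes lower with sgERG in 279 genes, where 1000 lists matched on mean CPM reached at most 268, and those at least 2-fold lower did so in 58 of 131, where matched lists reached at most 18, so expression level does not account for either overlap. In the other direction 20 of the 131 rose with sgERG, where matched lists had a median of 8 and a highest of 20. The odds ratio for genes lower with sgERG was 3.73 in genes lower with ETV6_WT than with ETV6_R399C, above the upper bound of 0.84 for genes lower with ETV6_R399C than with tagBFP, but the same genes were enriched for genes higher with sgERG (odds ratio 2.66, 95% interval 2.23 to 3.16) and genes higher with ETV6_R399C than with tagBFP for genes lower with sgERG (2.5), so over all genes an effect of any ETV6 construct cannot be told apart from one of the wild type. In the 2-fold set 54.6% of the 97 also lower than with ETV6_R399C fell, against 14.7% of the other 34 (odds ratio 6.89, 95% interval 2.37 to 24.7, Fisher's exact p = 4.5e-05). In the same 2 parts 13.4% and 20.6% rose (odds ratio 0.6, 0.197 to 1.96, Fisher's exact p = 0.405). Falls were thus more frequent among the genes also lower than with ETV6_R399C. The test counts genes, which are not independent, so it does not decide whether any ETV6 construct was the whole cause there. A candidate explanation is that wild-type ETV6 and ERG act in opposite directions on part of these genes. It does not predict that 17 of the 55 genes at least 2-fold higher with ETV6_WT than with ETV6_R399C also fell with sgERG and 6 rose (camera adjusted p = 0.0045, adjusted p = 0.151 with an estimated correlation). It stays open beside an effect of any ETV6 construct and the state of the wild-type cell population, and direct binding was not analysed here.

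With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real one. It called 5202 genes for ETV6_WT and 5826 for ETV6_R399C against tagBFP, where the highest other split called 1 in each. It called 3044 between the 2 forms, where the highest other called 2, and 1969 for sgERG, where the highest other called 1. Each other split mixes libraries of the 2 groups, so differences between the groups widen its spread and few calls are bound to follow. These numbers therefore do not measure how many genes would be called by chance.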

How the results depend on the processing

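The sets from the comparison with ETV6_R399C or from a 2-fold change, and the genes called against both tagBFP and ETV6_R399C, were chosen after seeing the data. Of 357 values that answer a comparison, taken under all alternatives, 320 were kept, 28 moved, 6 lost a call and 3 reversed. A count of genes or lists, a correlation or a covariance was kept if it stayed within 1.5-fold of the main value. Any other value was kept if its direction and, where tested, its side of the threshold stayed. For named genes 5002 of 5237 were kept, 231 lost a call and 4 reversed. For single lists 930 of 1062 were kept, 50 lost a call, 46 gained one and 36 moved, and of 89 list medians corrected for GC content and length 83 were kept and 6 moved. With DESeq2, median-of-ratios scaling, the stricter filter, all 15 libraries in 1 fit or only the 2 groups in the fit, every value run that answers a comparison was kept in this sense.

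With the transcript length offset the counts were 2913 for ETV6_WT and 3427 for ETV6_R399C against tagBFP and 1236 between the 2 forms, and the shared calls 1825; the cause was not tested. Genes both called and changed at least 2-fold numbered 382, 301, 203 and 267, fewer by construction, as did the 1290 called against both tagBFP and ETV6_R399C. Of named genes, IL1RAP (0.178) and VPS26C (-0.088) with ETV6_WT, BCL6 (-0.122) with ETV6_R399C and PDGFRB (0.114) between the 2 forms reversed with the length offset, and none was called there. Without the filter the covariance of the 2 forms was 0.559 and 8 lists were called with sgERG; the cause was not tested.

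Lists past the threshold with a preset correlation numbered 10 for ETV6_WT and 8 for ETV6_R399C against tagBFP, 8 between the forms and 5 with sgERG. With an estimated correlation they were 1, 1, 0 and 0, and B-lineage identity was the 1 in both. A higher correlation alone does not account for every lost call. With ETV6_WT the estimate was -0.001 for adhesion genes and -0.067 for NF-kB targets, below the preset 0.01. For other lists it lay above, up to 0.861 for mitochondrially encoded genes. With fry, which does not compare a list with other genes, they were 18 and 20 for the 2 forms and 11 with sgERG. For the genes lower with ETV6_WT, camera p in the sgERG fit was 0.16 for the set called against ETV6_R399C and 3.8e-07 for the 2-fold set, both turned downward. For the genes higher with ETV6_WT these were 0.913 and 0.771, both turned upward; the cause was not tested.

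Leaving out each library in turn, the counts ran from 4322 to 4813 for ETV6_WT and from 4865 to 5594 for ETV6_R399C against tagBFP. Between the forms they ran from 2008 (without ETV6_R399C replicate 1; 2009 without ETV6_WT replicate 2) to 3110. With sgERG they ran from 1160 (without sgCtrl replicate 1; 1162 without sgCtrl replicate 3) to 2302 without sgERG replicate 3. ETV6 ran from 6.308 to 6.376, 5.947 to 6.039, 0.332 to 0.401 and -1.07 to -0.922 on the log2 scale in the 4 comparisons, and ERG from 0.086 to 0.143, -0.014 to 0.028, 0.086 to 0.133 and -2.35 to -2.294. ERG, uncalled with ETV6_R399C against tagBFP, was below 0 without ETV6_R399C replicate 3 (-0.009), tagBFP replicate 1 (-0.014) or tagBFP replicate 2 (-0.002). Between the forms ERG lost its call without ETV6_R399C replicate 1 (edgeR adjusted p = 0.0572), ETV6_WT replicate 1 (0.073) or ETV6_WT replicate 2 (0.0628). The odds ratio for genes lower in both experiments ran from 1.35 to 1.83, and for genes higher in both from 1.76 to 2.81, the last without sgCtrl replicate 3. Camera p ran from 0.125 to 0.491 for the genes lower with ETV6_WT, and from 0.0239 to 0.0762 for those higher, above 0.05 without tagBFP replicate 2 (0.0526), sgERG replicate 2 (0.0632) or sgCtrl replicate 1 (0.0762). Shared calls ran from 3035 to 3471, r from 0.564 to 0.73 and the covariance from 0.161 to 0.246, the last without tagBFP replicate 1. Called lists numbered 8 to 11, 7 to 9, 7 to 9 and 3 to 6, with 3 without sgERG replicate 1.

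Some lists gained a call in camera. With a library left out these were endothelial genes with ETV6_WT against tagBFP without ETV6_WT replicate 3 (adjusted p = 0.0393) or tagBFP replicate 3 (0.0277), and with sgERG without sgERG replicate 3 (0.0312) or sgCtrl replicate 1 (0.0405). Cell cycle genes gained one with ETV6_R399C without its replicate 3 (0.0326) and with sgERG without sgERG replicate 3 (0.0312) or sgCtrl replicate 2 (0.0207). Mitochondrially encoded genes gained one between the forms without ETV6_WT replicate 3 (0.0045) and with sgERG without sgERG replicate 2 (0.0046). Without the filter on low counts the BCL2 family gained one with ETV6_R399C (0.0349), cell cycle genes with sgERG (0.0371) and mitochondrially encoded genes between the forms (0.0482), and with median-of-ratios scaling cell cycle genes with sgERG (0.0471).

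The replicate numbers did not pair the samples: correlations of same-numbered samples ran from -0.08 to 0.1, and not every sample correlated best with its own number. With the replicate block 5086, 5656, 2973 and 1536 genes were called in the 4 comparisons, and none of the values that answer a comparison changed its call. Among lists, the ETS family with ETV6_WT (camera adjusted p = 0.0505), myeloid genes with ETV6_R399C (0.0504) and neighbours of ERG with sgERG (0.052) were no longer called under the block, and mitochondrially encoded genes were called between the forms (0.0281). Of named genes 9 calls were lost, among them HLA-DRA and NFE2 with ETV6_WT, ESAM with ETV6_R399C, and AURKB, ESAM, FDFT1, PDGFRB and RRM2 with sgERG. Depth was 22040338 to 34046795 reads in the ETV6 experiment and 31881225 to 52481351 in the CRISPR interference experiment, with overlapping ranges. Every sgERG library (31881225 to 35735920 reads) was below every sgCtrl library (39873358 to 52481351), so depth and group cannot be separated there. Changes of genes near the filter rest on few reads.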

Other observations

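No test in this part was planned, and its values carry no explanation.

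Genes that changed with both forms of ETV6 took various levels in the sgCtrl cells of the other experiment, on a log2 CPM scale and without a test between experiments. TIAF1 stood at 4.35 in sgCtrl and 4.31 in tagBFP, against 7.27 with ETV6_WT and 7.18 with ETV6_R399C, and CD82 at 4.64 and 4.74, against 7.37 and 6.72. The tetraspanin gene CD9 stood at 5.93 in sgCtrl, above the 2.65 in tagBFP, the 4.73 with ETV6_WT and the 5.26 with ETV6_R399C. SCD had 73.9 CPM in tagBFP, 8.73 with ETV6_WT, 6.45 with ETV6_R399C and 0.039 in sgCtrl, where the 3 libraries held 5 reads in all. These SCD values are relative to the reads of named genes, without TMM scaling.

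The ETV6 transcripts differed unequally between the 2 forms. ETV6-202, which encodes the full protein of 452 codons, held 430.8 ± 18.2 RPM with ETV6_WT and 343.3 ± 11.8 with ETV6_R399C (SD, n = 3), a ratio of 0.797. ETV6-201, a transcript of 160 bases, held 13.2 ± 0.52 and 6.44 ± 0.76, a ratio of 0.487. The codon changed in R399C starts at base 32 of ETV6-201 and at base 1469 of ETV6-202, and the first 93 bases of ETV6-201 are shared with ETV6-202.

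The ERG transcripts that start between 38498442 and 38498483 held 271.2 ± 5.95 RPM with ETV6_WT, 256.5 ± 3.18 with ETV6_R399C and 249.7 ± 4.64 with tagBFP (SD, n = 3). RUNX1, chosen after its values were seen, was 0.15 higher with ETV6_WT than with tagBFP on the log2 scale (edgeR adjusted p = 0.0221) and differed by -0.25 between ETV6_WT and ETV6_R399C (edgeR adjusted p = 0.00257).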
